A study of Mus musculus with 20 samples.

How the data were processed

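Biotin-labelled RNA of 20 mouse cell samples was hybridised to Affymetrix arrays after One-Cycle labelling, per the labels' protocols. The deposited values were log2 intensities per probe set that the authors made with RMA, per the submitters' processing notes, which give no version, and Bioconductor is named in the samples' descriptions. RMA corrects background, normalizes quantiles between arrays and summarises the probes of a set. Whether all 20 arrays were processed together is not stated, and the ESC_like arrays carry later sample numbers than the rest. The log2 values had a median of 4.98 and the lowest correlation between any pair of arrays, across all probe sets, was 0.872. Across the tested genes it was 0.843, between a GSC and a MEF array. Values were used as deposited, with no further scaling and no missing value.

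Of 45101 probe sets, 64 controls were left out, 34945 had 1 gene symbol in the probe table, 932 had several and 9160 had none. Symbols were updated from a reference table of mouse genes through gene identifiers for 34741 probe sets. A gene was represented by the probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets.

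Group means were fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean for each of 6 groups and no covariate, so that the groups share 1 estimate of the spread per gene. The 7 comparisons were gPS minus GSC, gPS minus ESC, GSC minus ESC, gPS minus ESC_like, ESC_like minus ESC, gPS minus NSC and gPS minus MEF. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison and a difference of at least 2-fold. Errors marked SE are limma's moderated standard errors of log2 differences, and intervals are at 95%. The comparisons, the 20 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

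Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists of a comparison, and again with an estimated correlation and with fry. Fry asks whether a list moved at all, not whether it moved more than other genes. It made calls of 69 of the 140 list results that camera had not called, and left 71 as they were. A camera call that was lost with an estimated correlation is given with that p, and the other camera calls held. Of the list members, 7 of the 12 two-cell-like genes and up to 4 genes of any other list were not measured here. For each comparison the genes that could be named were 17 fixed genes, from each list up to 4 called members with the largest differences and up to 2 members not called with the smallest, and the 5 largest rises and 5 largest falls among genes whose groups do not overlap.

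Similarity to ESC was the mean Pearson correlation across genes with the 3 ESC arrays, compared by an exact permutation test. Feeder genes were those at least 4-fold higher in MEF than in NSC. The share of MEF level was computed on the linear scale from 46 genes with a MEF mean above 10 and more than 5 log2 units above ESC and NSC, with the ESC mean as 0 and the MEF mean as 100 percent. Chromosome medians were taken over genes whose highest group mean exceeded 7, relative to the ESC mean and to the array's median over all such genes, and compared with 10000 random lists matched on level.

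The fit was tested on simulated data with 18193 genes, 50 of them changed by each of several sizes. For gPS minus GSC it called 98% of the changes of 1.5 log2 units and 38% of those of exactly 1, and for gPS minus ESC 98% and 60%, with at most 1 false call. The simulation drew independent normal noise with 1 spread per gene for all arrays. It therefore does not measure power or false calls where groups differ in spread or genes vary together. Alternatives were quantile normalization, centring, array weights, a variance trend with robust fit, only the compared groups, ESC_like left out, Spearman correlation, the mean of a gene's probe sets, probe sets of shared suffix left out (names ending in x_at, s_at or a_at), dim genes or feeder genes left out, other thresholds, probe sets in place of genes, a replicate block and leaving out each array in turn. Added after seeing the data were leaving out gPS replicates 1 and 2 together, leaving out the genes of chromosomes 6, 8, 11 and Y, and list tests without feeder genes. 6 further lists (macrophage, glycolysis, oxidative phosphorylation, Hox, Rhox and Mage, and Wnt pathway) were chosen after the other results were seen. Their p-values were adjusted over these 6 lists of a comparison alone. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.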

Results

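Transcript levels were measured on 20 mouse arrays with 45101 probe sets each, and 18193 genes were tested. Germline stem cells (GSC, 3 arrays), the self-renewing cells that found spermatogenesis, came from the testes of mice carrying green fluorescent protein under the Oct4 promoter. Germline pluripotent stem cells (gPS, 5 arrays) were grown from round, bright colonies that had appeared after 3 to 4 weeks in wells plated with about 1000 GSC. Embryonic stem cells of the RW4 line (ESC, 3 arrays) and ESC-like cells from the testes of mice aged 0 to 2 days (ESC_like, 3 arrays), which another laboratory had provided, were both kept on fibroblast feeder cells with leukemia inhibitory factor. Neural stem cells made from Olig2-GFP embryonic stem cells (NSC, 3 arrays) and mouse embryonic fibroblasts of C3H embryos (MEF, 3 arrays) served as somatic references. Fibroblasts were also the feeder cells under GSC and gPS cells, as under ESC and ESC_like cells. The log2 intensities ran from 2.04 to 14.71, and the array medians from 4.95 to 5.04. Each array correlated with the rest of its group across all probe sets at a mean r of 0.979 in gPS replicate 1 to 0.997 in the MEF arrays. The difference between the 3' and 5' control probe sets of Actb, a sign of RNA integrity, was 1.25 (log2) in GSC replicate 1 and 0.51 and 0.49 in the other GSC arrays. The number of arrays limits the precision, and since the labels do not name separate cultures, the p-values measure only the spread between these samples.

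The first comparison asked what changed when pluripotent colonies arose from GSC. Nanog, a transcription factor of the pluripotency network, rose from 3.96 ± 0.13 (log2, SD, n = 3) in GSC to 11.66 ± 0.23 (SD, n = 5) in gPS cells. Tdgf1, a co-receptor of the Nodal pathway, rose from 3.85 to 11.96, Tet1, which oxidises 5-methylcytosine, from 3.77 to 10.62, and the nuclear receptor gene Nr0b1 from 3.13 to 9.75. Levels under or near the median of all values (4.98) may be background, so the size of a difference from such a level is uncertain. Pou5f1, which encodes Oct4, was expressed in GSC at 9.29 ± 0.21 (SD, n = 3) and rose to 12.502 ± 0.26 (SD, n = 5) in gPS cells. Of the 32 measured members of the pluripotency list, 28 rose, 0 fell and 4 were not called, with 28 called when adjusted over the list alone, and the list moved up against the other genes (median log2 difference 4.20, camera adjusted p = 1.08e-22). Nr5a2 was among the members not called, with a log2 difference of 0.30 ± 0.15 (SE). Of the 7 reprogramming factors, 5 rose, 0 fell and 2 were not called (5 adjusted over the list alone, adjusted p = 8.97e-05). Sox2 rose by 2.01 ± 0.13 (SE), Klf4 by 2.22 ± 0.23 (SE) and Myc by 3.59 ± 0.25 (SE) on the log2 scale, and Lin28a, an RNA-binding factor, differed by 0.03 ± 0.17 (SE).

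**Figure D1:**
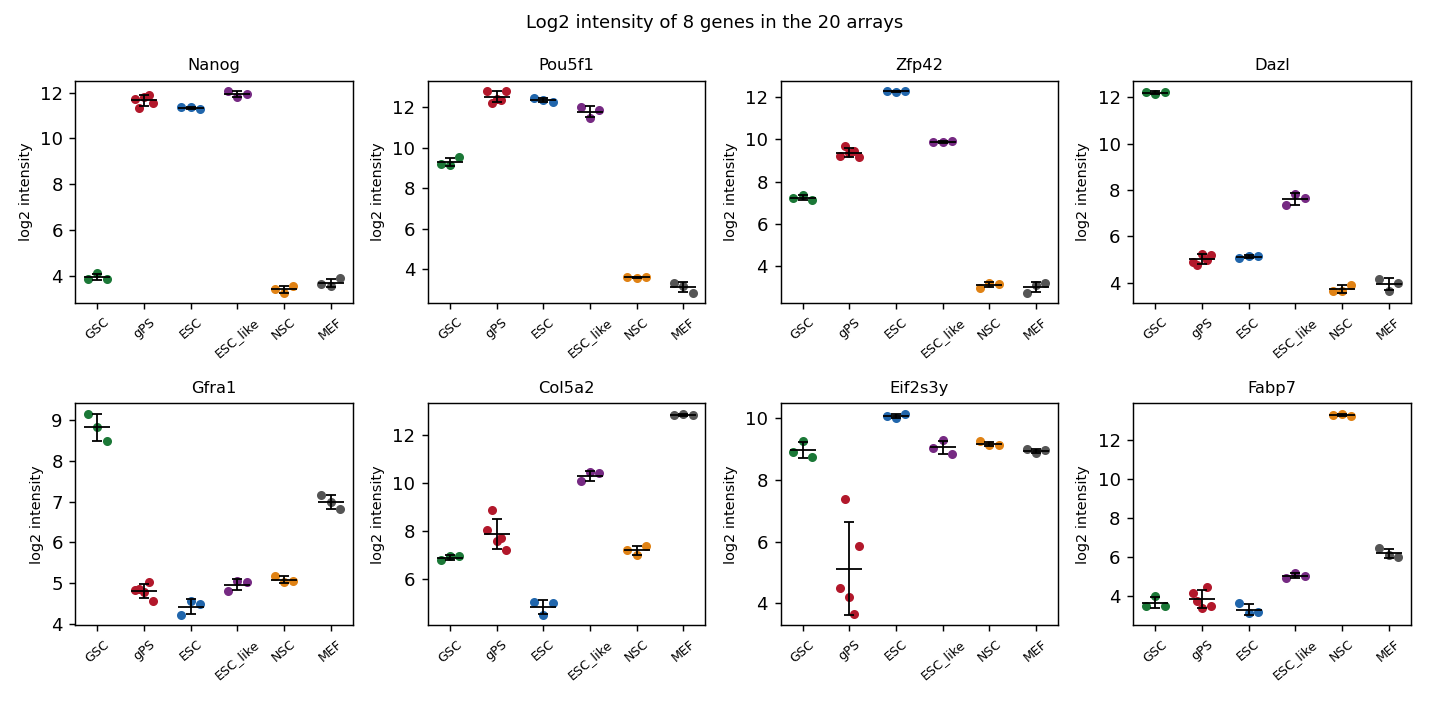
Log2 intensity of 8 genes in the 20 arrays, with the 6 cell groups on the horizontal axis; points are arrays and black marks are the group mean and SD. Nanog lay at a mean of 3.96 in GSC, 11.66 in gPS cells and 11.34 in ESC, and Dazl at 12.21, 5.01 and 5.12.

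Genes of the germ line fell in the same comparison. Dazl, an RNA-binding protein needed for germ cell development, fell from 12.21 ± 0.07 (log2, SD, n = 3) in GSC to 5.01 ± 0.20 (SD, n = 5) in gPS cells. Ddx4, the germ cell RNA helicase, fell by 4.57 ± 0.23 (SE) on the log2 scale, the germ cell surface protein gene Tex101 fell by 7.04 ± 0.12 (SE), and Mael, of the piRNA pathway, fell by 6.41 ± 0.30 (SE). Of the 21 measured members of the germ cell and piRNA pathway list, 20 fell and 1 was not called (20 adjusted over the list alone, median -4.55, adjusted p = 8.19e-19). The member not called was Kit, at -0.52 ± 0.27 (SE). Among 23 markers of undifferentiated spermatogonia, 13 fell, 2 rose and 8 were not called (15 adjusted over the list alone, median -1.78, adjusted p = 1.13e-04). Gfra1 and Ret, the receptor pair for the growth factor GDNF, fell by 4.02 ± 0.14 (SE) and fell by 3.40 ± 0.13 (SE), and Zbtb16 fell by 2.00 ± 0.16 (SE). Of 20 meiotic and postmeiotic genes, 11 fell and 9 were not called (11 adjusted over the list alone, median -1.30, adjusted p = 6.79e-05). Sycp2, of the synaptonemal complex, fell by 6.66 and the meiotic cohesin gene Smc1b fell by 5.79, and the protamine gene Prm1 differed by 0.03 ± 0.12 (SE). Slc25a31, an ADP/ATP carrier of germ cells, Tktl1, Nxf2, Uba1y and Taf7l headed the falls over all genes, at 11.24 to 12.11 in GSC and 3.36 to 4.38 in gPS cells, so that their order rests on background levels.

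Other fixed groups moved less uniformly between GSC and gPS cells. Of 28 cell cycle genes, 7 rose, 2 fell and 19 were not called (9 adjusted over the list alone, median 0.52, adjusted p = 1.13e-04). Rrm2, a subunit of ribonucleotide reductase, rose by 3.48 ± 0.14 (SE) and Ccne1 by 3.02 ± 0.18 (SE), while the cyclin gene Ccnd2 fell by 2.46 ± 0.17 (SE). On the Y chromosome and Xist list, 3 of 4 members fell (3 adjusted over the list alone, adjusted p = 0.107, and 0.0375 without gPS replicate 2). Eif2s3y fell by 3.84 ± 0.50 (SE), Kdm5d fell by 2.67 ± 0.19 (SE) and Uty fell by 1.43 ± 0.23 (SE), while the mean of the Uty probe sets changed by -0.68, which ends the call. The other probe sets of these genes disagreed in part, with changes up to -0.02 for Eif2s3y, -0.31 for Kdm5d and 0.14 for Uty. Of 22 paternally expressed imprinted genes, 10 rose, 4 fell and 8 were not called (14 adjusted over the list alone, adjusted p = 0.0663, and 0.0344 without gPS replicate 1 and 0.0375 without gPS replicate 2). Impact rose by 3.31 ± 0.16 (SE) and Mest by 2.20 ± 0.11 (SE), and Inpp5f fell by 2.38 ± 0.13 (SE). Of 25 genes of LIF, BMP, FGF and GDNF signalling, 10 rose and 5 fell (15 adjusted over the list alone, adjusted p = 0.319), and Stat3, the transcription factor downstream of LIF, fell by 2.68 ± 0.14 (SE). Of 27 DNA methylation and Polycomb genes, 7 rose and 5 fell (12 adjusted over the list alone, adjusted p = 0.107), with Dnmt3l, a cofactor of the de novo DNA methyltransferases, up by 5.51 ± 0.15 (SE) and the Polycomb gene Bmi1, which fell by 4.00 ± 0.21 (SE).

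In the primed epiblast list 7 of 13 genes rose and 3 fell (10 adjusted over the list alone, adjusted p = 0.107), with Otx2 up by 3.04 ± 0.28 (SE). Among 12 trophoblast genes 4 rose and 1 fell (5 adjusted over the list alone, adjusted p = 0.107, and 0.049 without gPS replicate 1), with Tfap2c up by 3.72 ± 0.46 (SE) and Krt8 up by 3.16 ± 0.26 (SE). Among 18 extraembryonic endoderm genes 4 rose and 3 fell (7 adjusted over the list alone, adjusted p = 0.337), with Apoe up by 2.81 ± 0.10 (SE) and Afp, which fell by 4.27 ± 0.15 (SE). Of 13 interferon and stress genes 2 rose and 3 fell (5 adjusted over the list alone, adjusted p = 0.319); the interferon-induced Oasl2 fell by 5.05 ± 0.21 (SE). Of 24 fibroblast and feeder genes 5 rose and 3 fell (8 adjusted over the list alone, adjusted p = 0.583), with Tagln up by 3.30 ± 0.19 (SE) and Col1a1 at -0.09 ± 0.26 (SE). Abundant fibroblast transcripts lay at a median of 0.619% to 1.08% of their MEF level in the GSC arrays and at 2.25% to 5.36% in the gPS arrays. Of 16 testis somatic cell genes 2 rose and 1 fell (3 adjusted over the list alone, adjusted p = 0.583), with Rhox5 up by 4.79 ± 0.48 (SE) and the Sertoli cell gene Wt1, which fell by 2.42 ± 0.21 (SE). In the neural stem cell list 2 of 21 genes rose and 1 fell, the transcription factor gene Zic1, by a change of -6.71 (3 adjusted over the list alone, adjusted p = 0.984). The rise of Olig1 (2.28) came from gPS replicates 1 and 2 and was 0.42 without them, and its call was lost without any 1 GSC array or with either of these left out. The mesoderm list had 1 fall among 15 genes (1 adjusted over the list alone, adjusted p = 0.988), the two-cell-like list 1 rise among 5 (1 adjusted over the list alone, adjusted p = 0.351), and the maternally expressed imprinted list 2 falls among 17 (2 adjusted over the list alone, adjusted p = 0.984). For the neural, mesoderm and maternally expressed lists the median was above 0 and the mean below it, with a test direction of down, up and up. In all, 3647 genes were called, 1655 higher and 1992 lower in gPS cells.

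**Figure D2:**
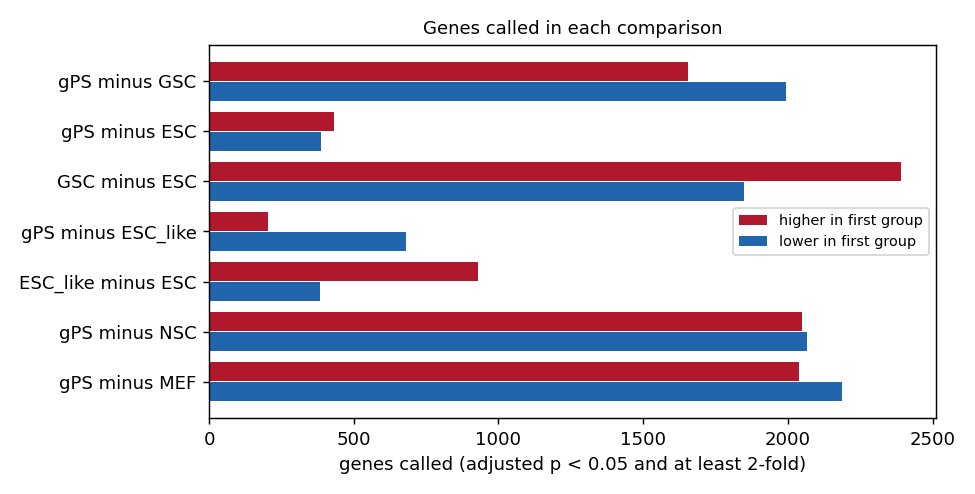
Number of genes called in each of the 7 comparisons, with bars for genes higher and lower in the first group named. The bars hold 1655 and 1992 genes for gPS minus GSC, and 430 and 387 for gPS minus ESC.

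The next comparison asked how far gPS cells lay from ESC. The core factors lay close: the log2 difference was 0.15 (95% confidence interval -0.16 to 0.46) for Pou5f1, 0.32 (0.06 to 0.58) for Nanog and -0.38 (-0.66 to -0.10) for Sox2, and none was called. Zfp42, also known as Rex1, was lower in gPS cells, at 9.38 ± 0.21 (log2, SD, n = 5) against 12.27 ± 0.02 (SD, n = 3), a 7.44-fold difference. Klf4 was 2.73-fold higher, and Lefty2, an antagonist of Nodal, was 3.50-fold higher. Dppa3, a maternal and germ cell factor, was 7.16-fold higher, with gPS replicate 1 at 7.62 and the other gPS arrays between 11.11 and 11.70. Of 32 pluripotency genes, 4 were higher, 3 lower and 25 not called (7 adjusted over the list alone, adjusted p = 0.251), and of the 7 reprogramming factors 1 was higher (1 adjusted over the list alone, adjusted p = 0.139). With fry both lists were called, pluripotency lower (fry adjusted p = 7.34e-04) and reprogramming factors higher (fry adjusted p = 4.43e-04). For Lin28a the probe sets disagreed, from -1.81 to 0.64.

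Most germ line genes did not separate gPS cells from ESC by the thresholds used. Dazl differed by -0.11 ± 0.13 (SE), Gfra1 by 0.39 ± 0.14 (SE), Ret by -0.06 ± 0.13 (SE) and Zbtb16 by -0.11 ± 0.16 (SE) on the log2 scale, and none was called. Of 21 germ cell and piRNA pathway genes 3 were higher and 1 lower (4 adjusted over the list alone, adjusted p = 0.251). Ddx4 was higher by 1.40 ± 0.23 (SE), at 7.23 in gPS cells, 5.83 in ESC and 7.17 in MEF. Of 23 spermatogonial genes 2 were higher and 1 lower (3 adjusted over the list alone, adjusted p = 0.570), with the ubiquitin hydrolase gene Uchl1 higher by 2.00 ± 0.15 (SE). Of 20 meiotic genes 2 were lower (2 adjusted over the list alone, adjusted p = 0.398), Sycp3 at -2.40 ± 0.20 (SE) and Stag3 at -1.54 ± 0.16 (SE). With fry all of these lists were called: germ cell (fry adjusted p = 0.0012) and spermatogonial (0.0118) higher, and meiotic (0.0012) lower.

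Fibroblast genes were higher in gPS cells than in ESC: 18 of 24 were called higher, 0 lower and 6 not called (18 adjusted over the list alone, median 1.82, adjusted p = 1.59e-20). The call held with an estimated correlation (adjusted p = 0.0408 with an estimated correlation). The collagen gene Col1a1 was higher by 2.65 ± 0.26 (SE) and Col5a2 by 3.04 ± 0.24 (SE). Col3a1 was higher by 3.89 ± 0.39 (SE) and Fbln2 by 2.88 ± 0.15 (SE), or by 0.60 and 0.17 with probe sets of shared suffix left out, which ends both calls. Abundant fibroblast transcripts had a median of -0.06% to 0.0116% of their MEF level in the ESC arrays, against 2.25% to 5.36% in the gPS arrays. The ESC mean is 0 on this scale by definition, so the ESC values do not measure feeder RNA in ESC. Mgp, the matrix Gla protein gene, was at 10.24 in gPS cells, 4.38 in ESC and 9.65 in MEF. Cd44, a hyaluronan receptor gene, was at 8.39, 3.32 and 11.92. Sox11 was 18.0-fold higher, and the matrix gene Tnc was at 8.33 in gPS cells and 4.28 in ESC. Pmel, a melanosome protein gene, was lower by a log2 difference of -5.18 ± 0.18 (SE), Serpinb6c by -5.30 ± 0.21 (SE) and Aass, of lysine breakdown, by -5.15 ± 0.14 (SE).

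Cell cycle genes were higher as a list, with 5 of 28 called higher, 0 lower and 23 not called (5 adjusted over the list alone, median 0.31, adjusted p = 1.13e-04, and adjusted p = 0.0408 with an estimated correlation). The members called included the cyclin genes Ccnd2, higher by 3.71 ± 0.17 (SE), and Ccnd1, by 2.38 ± 0.18 (SE), and the inhibitor gene Cdkn1a, by 1.46 ± 0.14 (SE), while Rrm2 differed by 0.09 ± 0.14 (SE). In MEF Ccnd2 was at 12.20 and Cdkn1a at 11.77. Of 22 paternally expressed imprinted genes 6 were higher and 0 lower (6 adjusted over the list alone, adjusted p = 0.0168, and adjusted p = 0.132 with an estimated correlation), with Nnat higher by 2.09 ± 0.37 (SE) and Peg12 by 1.27 ± 0.29 (SE). Of 17 maternally expressed genes 1 was higher and 3 lower (4 adjusted over the list alone, adjusted p = 0.165), with Rian, a noncoding RNA of the Dlk1-Gtl2 region, at -2.79 ± 0.19 (SE). Another, Phlda2 (-1.25 ± 0.43, SE), lost its call without any 1 ESC array and with ESC_like arrays left out of the fit (adjusted p = 0.057). Of 25 signalling genes 5 were lower (5 adjusted over the list alone, adjusted p = 0.139), including the growth factor genes Kitl at -2.71 ± 0.26 (SE) and Bmp4 at -2.27 ± 0.26 (SE), and the BMP target Id1 at -1.93 ± 0.16 (SE). Of 4 genes on the Y chromosome and Xist list 3 were lower (3 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.181 with an estimated correlation). Eif2s3y was at -4.95 ± 0.50 (SE) and Uty at -2.48 ± 0.23 (SE), while the third, Xist, had probe sets from -2.07 to 0.16. Kdm5d was at 3.04 in gPS cells and 2.75 in ESC. The extraembryonic endoderm list had 1 of 18 genes called, Lamb1 (1 adjusted over the list alone, adjusted p = 0.034, and adjusted p = 0.219 with an estimated correlation), and lost its call without gPS replicate 1 (0.0805) or replicate 5 (0.0563), or with feeder genes left out (0.3576). In all, 817 genes were called, 430 higher and 387 lower. The balance turned to 293 and 347 with feeder genes left out and to 371 and 398 with the replicate block. It also turned without ESC replicate 3 (389 and 436) and with probe sets in place of genes (782 and 898).

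The distance of GSC from ESC was measured in the same way. Nanog was at 3.96 in GSC and 11.34 in ESC, Tdgf1 at 3.85 and 12.10, and Tet1 at 3.77 and 11.06, while Sall4, a zinc finger factor of both stem cell types, differed by -0.11 ± 0.14 (log2, SE). Of 32 pluripotency genes 28 were lower and 4 not called (28 adjusted over the list alone, median -4.28, adjusted p = 1.14e-21), and of 21 germ cell genes 20 were higher and 1 not called (20 adjusted over the list alone, median 4.70, adjusted p = 2.64e-18). Dazl was at 12.21 in GSC and 5.12 in ESC, and Piwil2, of the piRNA pathway, at 11.38 and 5.03. Of 23 spermatogonial genes 12 were higher and 3 lower (15 adjusted over the list alone, adjusted p = 2.67e-04), and of 20 meiotic genes 10 were higher (10 adjusted over the list alone, adjusted p = 3.02e-04). Of 24 fibroblast genes 16 were higher and 8 not called (16 adjusted over the list alone, adjusted p = 1.68e-05, and adjusted p = 0.278 with an estimated correlation), while abundant fibroblast transcripts lay at 0.619% to 1.08% of their MEF level in GSC. Of 13 interferon and stress genes 5 were higher and 1 lower (6 adjusted over the list alone, adjusted p = 0.0327, 0.1878 with feeder genes left out, and adjusted p = 0.0602 with an estimated correlation). In all, 4241 genes were called, 2392 higher and 1849 lower in GSC.

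Of the 4241 genes called between GSC and ESC, 500 were called in the same direction between gPS cells and ESC (11.8%), 223 higher and 277 lower, and 51 in the opposite direction. Independent lists of these sizes would share 95.9 genes, and simulated groups without any difference from ESC, which leave out real effects and so could share hardly any call, shared 0 in 100 simulations. Part of the excess may come from the ESC arrays that both comparisons share. The 95% interval of the difference from ESC lay within 2-fold for 16111 of 18193 genes in gPS cells (88.6%), 15322 in ESC_like cells (84.2%) and 11870 in GSC (65.2%), where the 5 gPS arrays give narrower intervals than 3. All groups shared 1 estimate of the spread per gene, which can make intervals, SE and p too small for a group that varies more. The array weights, lower for arrays that vary more, were 0.187 to 1.03 in gPS and 1.24 to 3.29 in ESC_like cells. Only 13301 of the genes had a group mean above the median of all values (4.98). Genes at background in every group can count as alike. The order of gPS and ESC_like cells turned with only the compared groups in the fit, at 15571 (85.6%) and 15968 (87.8%).

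The comparison with ESC_like cells set gPS cells beside pluripotent cells from newborn testis. Nanog differed by -0.27 ± 0.12 (log2, SE), Sox2 by -0.13 ± 0.13 (SE) and Esrrb by 0.01 ± 0.14 (SE), none called, and of 32 pluripotency genes 2 were higher and 1 lower in gPS cells (3 adjusted over the list alone, adjusted p = 0.952). Trh, a thyrotropin-releasing hormone gene active in ESC, was 5.03-fold higher, and Prdm14, a transcriptional regulator of naive pluripotency and germ cells, was lower by a difference of -1.29 ± 0.18 (SE). Of 21 germ cell genes 3 were higher and 4 lower (7 adjusted over the list alone, adjusted p = 0.917): Ddx4 was 3.51-fold higher, and Dazl was at 5.01 ± 0.20 (SD, n = 5) in gPS cells and 7.60 ± 0.25 (SD, n = 3) in ESC_like cells. Of 24 fibroblast genes 16 were lower and 8 not called (16 adjusted over the list alone, median -1.24, adjusted p = 4.69e-16, and adjusted p = 0.0639 with an estimated correlation), among them Col5a2 at -2.42 ± 0.24 (SE) and Lox, which cross-links collagen, at -2.39 ± 0.19 (SE). Abundant fibroblast transcripts lay at 10.5% to 12.52% of their MEF level in the ESC_like arrays and at 2.25% to 5.36% in the gPS arrays. Of 13 interferon and stress genes 6 were lower (6 adjusted over the list alone, median -0.93, adjusted p = 4.18e-06), including Jun at -1.80 ± 0.36 (SE), Atf3 at -1.60 ± 0.17 (SE) and Oas1a at -1.37 ± 0.12 (SE). In MEF Jun was at 9.31 and Atf3 at 5.56, against 9.37 and 8.22 in ESC_like cells.

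Other genes also separated the testis-derived lines. Of 17 maternally expressed imprinted genes 4 were lower in gPS cells (4 adjusted over the list alone, adjusted p = 0.136, but 0.0338 with the mean of probe sets and 0.0267 without gPS replicates 1 and 2, both of which make it a call), including Meg3 at -2.61 ± 0.30 (SE), Grb10 at -1.87 ± 0.30 (SE) and Rian at -1.87 ± 0.19 (SE). Of 25 signalling genes 3 were lower (3 adjusted over the list alone, adjusted p = 0.0156, 0.0707 after quantile normalization, 0.0894 with feeder genes left out, and adjusted p = 0.121 with an estimated correlation), including Bmp4 at -2.34 ± 0.26 (SE). Of 4 genes on the Y chromosome and Xist list 3 were lower (3 adjusted over the list alone, adjusted p = 5.23e-04, and adjusted p = 0.154 with an estimated correlation), with Eif2s3y at -3.93 ± 0.50 (SE). Pnma5 at -4.20 ± 0.12 (SE) and Fmr1nb at -4.16 ± 0.18 (SE) were among the genes with the largest falls, and Sox11, a factor of neural progenitors, rose by 3.18 ± 0.20 (SE). Median, mean and test differed in sign for 8 of the 20 lists, none of which was called. In all, 882 genes were called, 202 higher and 680 lower in gPS cells. This balance depended on the setting: with no minimum fold 2696 were higher and 2643 lower, and 361 were higher and 723 lower without gPS replicates 1 and 2.

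ESC_like cells were also compared with ESC. Zfp42 was at 9.89 ± 0.04 (log2, SD, n = 3) against 12.27 ± 0.02 (SD, n = 3), a 5.22-fold difference, Klf4 was 3.45-fold higher, and of 32 pluripotency genes 2 were higher and 4 lower (6 adjusted over the list alone, adjusted p = 0.338). Dazl was at 7.60 in ESC_like cells and 5.12 in ESC, Tex19.1 was 6.62-fold higher, and of 21 germ cell genes 3 were higher (3 adjusted over the list alone, adjusted p = 0.181). Of 24 fibroblast genes 21 were higher and 3 not called (21 adjusted over the list alone, median 3.31, adjusted p = 7.03e-30, and adjusted p = 0.0061 with an estimated correlation), with Col5a2 higher by 5.47 ± 0.27 (SE) and Lox by 5.00 ± 0.21 (SE), beside the 10.5% to 12.52% of MEF level for abundant fibroblast transcripts. Of 13 interferon and stress genes 8 were higher (8 adjusted over the list alone, median 1.18, adjusted p = 7.52e-07, and adjusted p = 0.0011 with an estimated correlation), including the immediate early genes Fos, by 4.46 ± 0.21 (SE), and Egr1, by 3.35 ± 0.31 (SE), whose MEF levels were 8.87 and 9.91. Of 22 paternally expressed imprinted genes 6 were higher (6 adjusted over the list alone, adjusted p = 0.0101, and adjusted p = 0.0914 with an estimated correlation), including Ndn by 2.36 ± 0.15 (SE). Of 28 cell cycle genes 6 were higher (6 adjusted over the list alone, adjusted p = 0.0042, and adjusted p = 0.0914 with an estimated correlation), including Ccnd2 by 5.51 ± 0.19 (SE). In all, 1312 genes were called, 930 higher and 382 lower. Higher calls also led in other settings, by differing margins: 2740 and 2391 with no minimum fold, 623 and 358 with feeder genes left out, and 355 and 88 with treat against 2-fold.

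The mean correlation with the 3 ESC arrays, across 18193 genes that are not independent replicates, was 0.972 ± 0.0035 (SD, n = 5) for gPS cells and 0.964 ± 0.0014 (SD, n = 3) for ESC_like cells. The difference of 0.0072 had an exact two-sided permutation p of 0.0357 over 56 arrangements. The exact permutation p was 0.0571 without gPS replicate 2, 3, 4 or 5, 0.0536 without ESC replicate 3, and 0.0952 without ESC_like replicate 2 or 3. With 748 feeder genes left out, the means were 0.975 and 0.974 and the exact permutation p was 0.661. The mean correlation was 0.901 between gPS cells and GSC, 0.887 between GSC and ESC, and 0.880 between gPS cells and MEF.

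**Figure D3:**
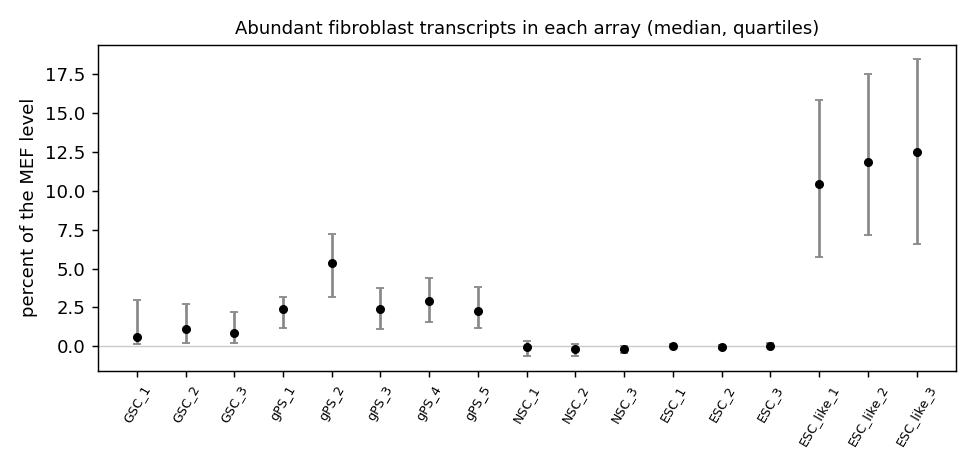
Level of 46 abundant fibroblast genes as a percent of their MEF level in 17 arrays; points are medians and bars the lower to upper quartile. The ESC_like arrays sit at 10.5% to 12.52%, gPS replicate 2 at 5.36%, and the other gPS arrays at 2.25% to 2.88%.

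Against NSC, most pluripotency genes were higher in gPS cells and 15 of 21 neural genes were lower. Pou5f1 was at 12.502 ± 0.26 (log2, SD, n = 5) against 3.61 ± 0.03 (SD, n = 3), and Sox2, expressed in both stem cell types, differed by 0.30 ± 0.13 (SE). Of 32 pluripotency genes 30 were higher and 2 not called (30 adjusted over the list alone, median 5.68, adjusted p = 6.01e-25). Of 21 neural stem cell genes 15 were lower and 6 not called (15 adjusted over the list alone, median -2.72, adjusted p = 8.96e-10), with Fabp7, a fatty acid binding protein of radial glia, at -9.43 ± 0.20 (SE) and the proteoglycan gene Bcan at -6.75 ± 0.15 (SE). Olig2, tagged in the source line, was at 4.16 ± 1.25 (SD, n = 5) and 11.59 ± 0.13 (SD, n = 3). Of 21 germ cell genes 13 were higher and 1 lower (14 adjusted over the list alone, adjusted p = 8.43e-05), and of 27 DNA methylation and Polycomb genes 13 were higher and 1 lower (14 adjusted over the list alone, adjusted p = 8.43e-05), including Dnmt3l by 7.13 ± 0.15 (SE). The trophoblast list had 5 of 12 genes higher (5 adjusted over the list alone, adjusted p = 0.0458, 0.0575 after quantile normalization, 0.1204 with feeder genes left out, and adjusted p = 0.245 with an estimated correlation). In all, 4113 genes were called, 2048 higher and 2065 lower. This near balance turned in several settings, to 5464 and 4105 with no minimum fold, for example.

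Against MEF, 32 of 32 pluripotency genes were higher in gPS cells (32 adjusted over the list alone, median 6.17, adjusted p = 4.39e-26) and 24 of 24 fibroblast genes were lower (24 adjusted over the list alone, median -3.75, adjusted p = 2.59e-18). Dppa5a, a marker of ESC, was 366-fold higher, L1td1 was at 11.88 in gPS cells and under 4.98 in MEF, and Pdgfra was at -4.87 ± 0.13 (log2, SE) and Lox at -5.53 ± 0.19 (SE). Of 27 DNA methylation and Polycomb genes 19 were higher and 1 lower (20 adjusted over the list alone, adjusted p = 8.34e-08), of 21 germ cell genes 13 were higher and 1 lower (14 adjusted over the list alone, adjusted p = 1.08e-04), and of 13 primed epiblast genes 7 were higher and 1 lower (8 adjusted over the list alone, adjusted p = 0.0089). Among imprinted genes Igf2, a fetal growth factor, was at -3.99 ± 0.24 (SE) and Rian at -4.75 ± 0.19 (SE). Of the Y chromosome and Xist list 4 of 4 members were lower (4 adjusted over the list alone, adjusted p = 0.0073, 0.068 with feeder genes left out, and adjusted p = 0.168 with an estimated correlation), with Eif2s3y at -3.82 ± 0.50 (SE) and Kdm5d at -2.69 ± 0.19 (SE). In all, 4226 genes were called, 2040 higher and 2186 lower. Higher calls led with feeder genes left out (2006 and 1590), without gPS replicates 1 and 2 (2216 and 2161) and with no minimum fold (5495 and 4214). Feeder genes were chosen as high in MEF, so leaving them out removes lower calls by construction. Median, mean and test differed in sign for 2 of the 20 lists against MEF, 2 against NSC, 2 in gPS minus ESC, 1 in GSC minus ESC and 6 in ESC_like minus ESC, none of them called.

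**Figure D4:**
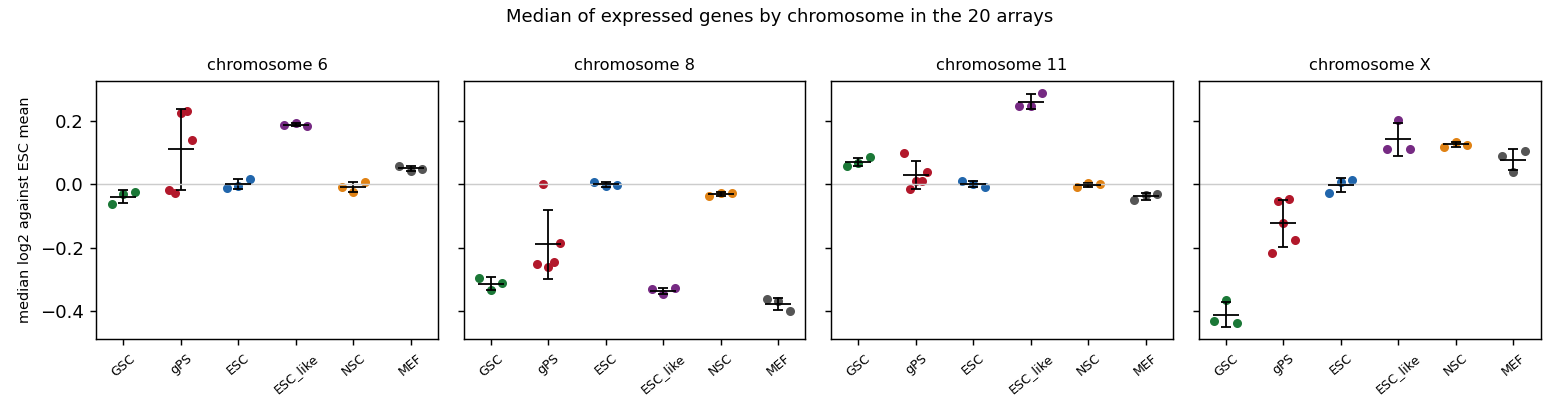
Median log2 difference from the ESC mean of expressed genes on chromosomes 6, 8, 11 and X, with the cell groups on the horizontal axis; points are arrays and black marks are the group mean and SD. On chromosome 8 the MEF arrays lie at -0.36 to -0.40, and the NSC arrays at -0.03 to -0.04.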

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

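The tests of the Y-linked and the fibroblast transcripts were chosen after the result was seen, and the splits of the arrays were planned before.

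Among 152 values of gPS cells examined, 17 had 1 array far from the other 4, 12 of them in replicate 1 and 5 in replicate 2; chance gives such an array in about 1 in 20 groups. In replicate 1 the log2 level was below the other arrays for Baiap2l1 (6.77), Bmi1 (5.04), Dppa3 (7.62), Tcl1 (8.72) and Tfap2c (7.18). It was above them for Ccne1 (10.49), Esrrb (9.53), Klf4 (11.72), Mael (6.72), Mirg (5.53), Myc (9.31) and Stat3 (9.06). In replicate 2 it was above them for Cavin2 (7.19), Grb10 (9.23), Kdm5d (3.54) and Mgp (11.76), as was the median percent of the MEF level of abundant fibroblast transcripts (5.36). With both replicates left out, gPS minus GSC called 3740 genes and gPS minus ESC 1029.

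3 named genes were called in opposite directions in gPS and ESC_like cells against ESC, a choice that makes the difference between the lines at least 2 log2 units, so it was not tested further. For Meg3 it was -2.61 (gPS minus ESC -1.27, ESC_like minus ESC 1.34, or -0.49 and 0.91 as the mean of the probe sets, neither then called). For Pnma5 it was -4.20 (-1.06 and 3.14), and for Pramel7 it was -4.43 (-1.05 and 3.38), though -0.47 with probe sets of shared suffix left out. In gPS cells and ESC Pnma5 was at 4.51 and 5.56 and Pramel7 at 3.53 and 4.59, under or near the median of all values (4.98), so the lower level in gPS cells is not shown above background. Gm20767, Mitf and Pramel6, noticed after their values were seen, showed the same.

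Only the real split of the 8 arrays, 1 of 56, called as many genes in each of 5 comparisons. Other splits mix the cell groups and so raise the spread, which made lower counts likely beforehand. Since the labels do not name separate cultures, the splits cannot tell a group difference from one between lines or cultures, and they do not exclude chance. The real and highest other counts were 3647 and 1339 for gPS minus GSC, 817 and 499 for gPS minus ESC, 882 and 492 for gPS minus ESC_like, 4113 and 1804 for gPS minus NSC, and 4226 and 2004 for gPS minus MEF. For GSC minus ESC (4241, highest other 0) and ESC_like minus ESC (1312, highest other 0) the 10 splits are too few for a share under 5%.

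Y-linked transcripts were low in gPS cells, with Eif2s3y at 4.51, 7.39, 4.21, 3.67 and 5.85 in the 5 arrays against 8.74 to 9.26 in GSC. A strain variant under the probes is argued against for Eif2s3y and Uty, since gPS cells arose from GSC and their brightest probe sets fell, with a smallest change of -1.43. Kdm5d fell too, but its brightest probe set lay at 2.75 in ESC and 2.73 in NSC, where Eif2s3y was at 10.08 and 9.17. A low Kdm5d therefore does not count against a strain variant. Probe sets that changed by -0.02 (Eif2s3y), -0.31 (Kdm5d) and 0.14 (Uty) lay at 3.13, 4.00 and 2.62 in GSC, near background. The mean of the Uty probe sets ends its call. Female cells with a pair of active X chromosomes are argued against, as the X-linked medians relative to ESC were below 0 in every gPS array (highest -0.0457). This takes ESC, with Eif2s3y at 10.08, as male. The rule chosen for the test also asked for medians no higher than in GSC (-0.44 to -0.37), which was not met. ESC, at -0.0278 to 0.0144, lay above GSC too, so that part of the rule does not separate the explanations. In replicate 2 Eif2s3y would need 32.2% of the MEF level, beyond the 9.73% that 90 percent of abundant fibroblast transcripts stayed under, so male feeder RNA alone is unlikely as its source. Loss of the Y chromosome from most cells of the gPS cultures may also account for the pattern, a hypothesis that DNA copy number would test.

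Fibroblast genes were higher in gPS and ESC_like cells than in ESC. RNA of feeder cells is a candidate source: 95.7% of the abundant MEF genes lay above the highest ESC array in gPS cells and 97.8% did in ESC_like cells. These genes were chosen to lie low in ESC, which favours such a count. A mixture with 2.76% and 11.4% of MEF RNA would raise 74 of the 430 genes higher in gPS cells and 319 of the 930 in ESC_like cells at least 2-fold, and Mgp, at 10.24 in gPS cells and 9.65 in MEF, exceeds any mixture of ESC with these MEF. Quantile normalization and median centring kept 806 and 808 of the 817 gPS minus ESC calls and 1219 and 1303 of the 1312 ESC_like minus ESC calls. Quantile normalization changed the ESC_like minus ESC calls to 848 higher and 449 lower, and the fibroblast list stayed called in both comparisons. Both settings start from values already normalized by RMA, so the normalization of the raw intensities stays open. Differentiated cells within the cultures and differences between the lines stay open, untested.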

How the results depend on the processing

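Leaving out gPS replicates 1 and 2, leaving out chromosomes and list tests without feeder genes were chosen after seeing the data; the other settings were planned. With no minimum fold, the counts of genes called in the order of the report (gPS minus GSC, gPS minus ESC, GSC minus ESC, gPS minus ESC_like, ESC_like minus ESC, gPS minus NSC, gPS minus MEF) were 9253, 4555, 9143, 5339, 5131, 9569 and 9709. With treat against 2-fold they were 2101, 203, 2483, 199, 443, 2541 and 2684, and with probe sets in place of genes 6847, 1680, 8203, 1868, 2636, 8069 and 8208. These settings change the threshold or the number of tests by construction. Treat left 129 of the differences from GSC kept in gPS cells, and leaving out dim genes left 7196 GSC genes within 2-fold of ESC, of 13301 tested. All other settings run kept these counts within 1.5 times, but not always the same genes. With the mean of a gene's probe sets, 528 of the 817 gPS minus ESC calls were shared. The same setting shared 567 of the 882 gPS minus ESC_like calls and 2706 of the 3647 gPS minus GSC calls. With only the compared groups in the fit, fewer genes lay within 2-fold of ESC in gPS cells (15571) than in ESC_like cells (15968). With each array left out the counts ran over 3574-3724, 788-908, 4151-4332, 842-943, 1273-1365, 4064-4179 and 4187-4317, and the kept differences over 488-537. The greater similarity of gPS cells to ESC ran over 0.0063-0.0083 (exact permutation p 0.0286 to 0.0952), and the call was lost in 7 of these settings. Without a gPS or ESC_like array fewer than 56 arrangements remain, which by itself can raise the p. Without ESC replicate 3 the cause was not tested. The difference fell to 0.0012 (exact permutation p = 0.661) without feeder genes, so it rested largely on these genes. Whether their transcripts came from feeder cells or from the lines themselves was not tested here. With probe sets of shared suffix left out, another probe set represented the gene, and the sign turned for Plagl1 (gPS minus ESC -0.0812, ESC_like minus ESC -0.2068) and Dpys (gPS minus ESC 0.1310). With the replicate block the counts were 3681, 769, 4242, 869, 1314, 4036 and 4155, with 668 of the 817 gPS minus ESC calls shared, and Tex19.1 (0.94), Tdrd5 (0.96), Igf2 (0.92) and Phlda2 (-0.72) no longer called in gPS minus ESC, nor Mirg (-0.99) in gPS minus ESC_like, which changes the germ cell and imprinted counts; the cause was not tested. Phlda2 (gPS minus ESC), Olig2 (gPS minus ESC_like) and Olig1 (gPS minus GSC) lost their calls in many other settings too. Numbers did not pair the arrays, as 7 of 45 same-numbered pairs had r above 0.1 (median 0.0203). Signal near background limits dim genes.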

Other observations

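The lists and tests of this part were all chosen after the main results were seen, and no list here was among those fixed beforehand. The p-values of the lists do not allow for this choice from the same data, so they describe the lists and give no independent support.

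Genes of glycolysis separated GSC from gPS cells and ESC. Of 13 measured, 11 rose from GSC to gPS cells (11 adjusted over the list alone, median 2.85, adjusted p = 2.32e-10, and adjusted p = 0.0308 with an estimated correlation). Pfkl, the liver phosphofructokinase, rose by 4.96 ± 0.24 (log2, SE), the phosphoglycerate kinase Pgk1 by 3.90 ± 0.09 (SE) and the lactate dehydrogenase Ldha by 2.85 ± 0.11 (SE). Against ESC, 12 were lower and 1 higher in GSC (13 adjusted over the list alone, adjusted p = 9.94e-10, and adjusted p = 0.0383 with an estimated correlation), and 1 of 13 was called, lower, between gPS cells and ESC (adjusted p = 0.6115). The list was lower in ESC_like cells than in ESC with 0 of 13 genes called (adjusted p = 0.0263, and 0.421 with an estimated correlation), and higher in gPS cells than in NSC (9.63e-07 and 0.120) and MEF (2.91e-04 and 0.209). Of 15 oxidative phosphorylation genes 1 rose from GSC to gPS cells (adjusted p = 0.709).

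Of 15 macrophage genes 8 were higher in ESC_like cells than in ESC (8 adjusted over the list alone, adjusted p = 4.95e-06, and adjusted p = 0.207 with an estimated correlation). In GSC 7 were higher and 2 lower than in ESC (adjusted p = 0.0229, and adjusted p = 0.677 with an estimated correlation). The complement gene C1qb was higher by 2.07 ± 0.30 (log2, SE) in ESC_like cells and by 3.51 ± 0.30 (SE) in GSC, and the lysozyme gene Lyz2 by 5.15 ± 0.57 (SE) and 6.16 ± 0.57 (SE). Lyz2 was at 8.33 in MEF, so feeder cells may also express it. From ESC_like to gPS cells 8 macrophage genes were lower (adjusted p = 5.43e-08, and adjusted p = 0.0973 with an estimated correlation), from GSC 7 were lower and 1 higher (0.0063 and 0.431), and from MEF 5 were lower and 1 higher (0.0279 and 0.393). Of 13 Hox genes 5 were lower in gPS cells than in MEF (adjusted p = 1.26e-04, and adjusted p = 0.0248 with an estimated correlation). Between GSC and gPS cells, of 8 genes of the Rhox and Mage families 3 rose and 2 fell (adjusted p = 0.709), and of 15 Wnt pathway genes 4 rose and 1 fell (adjusted p = 0.242). The Rhox and Mage list was lower in gPS than in ESC_like cells (adjusted p = 0.0066, and 0.186 with an estimated correlation) and higher in ESC_like cells than in ESC (0.0459 and 0.421). Over the 7 comparisons 13 of the 42 tests of these 6 lists were called, and 3 of those held with an estimated correlation.

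Olig1 was at 9.44 and 8.05 in gPS replicates 1 and 2 and at 3.82 to 4.38 in the other gPS arrays. The chromosome 6 median against ESC was -0.0176 and -0.0286 in gPS replicates 1 and 2, 0.225, 0.233 and 0.142 in replicates 3 to 5, and 0.185 to 0.195 in ESC_like cells. In gPS replicates 3 to 5 the first of 3 parts of chromosome 6 lay at -0.0253 to -0.0161 and the others at 0.164 to 0.410, while in ESC_like cells all 3 parts lay above 0. The chromosome 11 median was 0.248 to 0.291 in ESC_like cells, and in gPS replicate 1 chromosome 10 lay at -0.236 and chromosome 3 at -0.192.

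The median of 522 expressed chromosome 8 genes lay below ESC by a log2 difference of -0.32 in GSC, -0.19 in gPS cells and -0.34 in ESC_like cells, with single gPS arrays from -0.26 to 3.00e-04. A few genes or 1 region are argued against in GSC and ESC_like cells, where the part of the chromosome nearest to 0 among 3 parts was at -0.24; in gPS cells it was at -0.14, no lower than an NSC part, which keeps this open. RNA of feeder cells is argued against, as a mixture of ESC and MEF would need at least 54.6% of MEF RNA. In every array of these groups, 90 percent of abundant fibroblast transcripts stayed under 26.3%. Of the random lists 0% reached the median, but such lists treat genes as independent. They also set ESC replicate 1 apart from the ESC mean on the X chromosome (-0.0278, with 0% at or below). A chance choice of genes is therefore not decided by them. On chromosome 8 the ESC arrays lay at -0.0055 to 0.0088. MEF lay at -0.36 to -0.40, and NSC at -0.03 to -0.04 with parts from -0.15 to 0.19. An extra chromosome 8 in the ESC line may be proposed, a hypothesis not tested against DNA, which by itself accounts for neither NSC nor gPS replicate 2.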
